A study of Homo sapiens with 3 samples.

How the data were processed

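RNA-seq libraries of 3 replicates of wild-type pNPCs, derived from the human embryonic stem cell line H1, were analysed as 1 group, as the sample titles give it. Per the labels, polyadenylated RNA was isolated with RNeasy columns and libraries were made with a NEBNext Ultra II DNA Library Prep kit. Strandedness and read layout are not given in the sources used here. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

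The submitters' processing notes name Trim Galore 0.6.10, STAR 2.7.11a, RSEM 1.3.1 and the GRCh38 build, with no role or order. The annotation release is not given in the sources used here. Per the file headers, each sample has an RSEM gene table of 62754 genes with length, effective length, expected count, TPM and FPKM. The deposited expected count is an estimate of the reads per gene, not normalized, and at least 86.8% of values in each library were exact whole numbers. The deposited TPM values were scaled by the authors for effective length to the same sum in each library, and the deposited FPKM values, scaled for length and for the reads of a library, were used only in an alternative. RSEM divides reads that fit several genes among them, so genes with close copies and overlapping genes carry extra uncertainty, and TPM compares genes within a library only as far as its length model holds.

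Totals were 34658454, 38400092 and 30038114 expected counts. Protein-coding genes took 96.9%, 97.4% and 96.8% of counts, and the 10 highest genes 5.45%, 4.53% and 4.57%. TPM of at least 1 was reached by 15349, 15541 and 16115 genes in replicates 1, 2 and 3. Gene types and transcript GC content came from GENCODE release 29, matched by identifier without its version for 58261 of the identifiers (92.8%), which held 99.5% of all counts and 19855 protein-coding genes. Printed coordinates are 1-based and come from the RefSeq gene table of GRCh38.p14. A gene with 0 counts in all libraries is given with the TPM that 3 counts would have had, taken in the library where this is highest. Libraries were compared in pairs by a chi-square of counts over genes with at least 20 counts in the pair.

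Before the data were examined, 32 gene lists with 487 genes were fixed. Identity lists were neural progenitor, pluripotency, mesoderm, endoderm, epidermis and placode, and neural crest. Regional lists were forebrain, midbrain and isthmus, hindbrain and spinal cord, and dorsoventral lists were roof plate and dorsal, and floor plate and ventral neural tube. Lineage lists, which also mark other cell types a culture could hold, were neuron, astrocyte and radial glia, oligodendrocyte lineage, microglia and macrophage, mesenchyme and fibroblast, endothelium, and red blood cell and platelet. The other lists covered proliferation, p53 targets and stress, the FGF, WNT, LIF, TGF-beta, retinoid, NOTCH and ROCK pathways, ligands of microglial receptors, neurotrophic and gliogenic ligands, neuron-glia adhesion and the interferon response. The tests, the alternatives and the naming rule were fixed at the same time. By that rule each list names its 3 members of highest mean TPM and up to 2 undetected members of lowest mean TPM (ties by alphabet), and detected members of the regional and dorsoventral lists may all be named. A few genes that the rule names are not reported here. The rule also names the 10 protein-coding genes of highest mean TPM and the 10 genes with the smallest adjusted p for excess spread.

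For each list and library the median of log2(TPM + 1), a pseudocount of 1, was taken, and 15 differences of list medians within a library were tested over the 3 libraries with an exact two-sided sign-flip permutation test and adjusted by Benjamini-Hochberg. Such differences are on the log2(TPM + 1) scale, which understates differences of low genes. A list's percentile is the place of its mean median among 10000 random lists of the same size drawn from protein-coding genes, as a description of these libraries. Excess spread was tested in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on expected counts rounded to whole numbers, with TMM scaling and filterByExpr, by an intercept-only negative binomial fit whose residual deviance was compared with a chi-square with 2 degrees of freedom at the trended dispersion, at a Benjamini-Hochberg threshold of 0.05. The common biological coefficient of variation was 22.6%. Deviations of a library are its log2 CPM minus the mean of the other 2. Lists were summarised with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

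The spread test was tested on simulated data with 1 library of each of 200 genes changed. With dispersions on the trend (16664 genes tested) it recovered 10%, 76%, 98% and 94% of genes changed 2-, 4-, 8- and 16-fold and called 2 others. With dispersions that varied between genes (16394 genes tested) it recovered 4%, 50%, 94% and 96% and called 198 others. The moderated F test recovered 2%, 66%, 92% and 94% with 0 others called in the first case, and 0% at each fold in the second.

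Alternatives were other TPM minimums, pseudocounts, units, scalings, filters, tests and summary statistics, members of no other list, the leaving out of mitochondrially encoded genes and of each replicate in turn, and, added after the data were seen, removal of a smooth (loess) trend of counts on transcript length or GC content in each library, with DESeq2 1.42.0 for dispersion outliers. Levels of sex-linked marker genes were left out. Single-cell or chimera data of the wider study were not used here.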

Results

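Polyadenylated RNA was sequenced from primitive neural progenitor cells (pNPCs), an early, self-renewing neural stage, that had been derived from H1, an established line of human embryonic stem cells. The series belongs to work on chimeric brain models of interactions among human neurons, macroglia and microglia, and the labels give 1 group of 3 wild-type replicates. No comparison between groups exists in this design, so gene lists fixed from the cell type, the medium and the subject of the series were compared with each other within each library, and the spread between replicates was measured. The libraries held 34658454, 38400092 and 30038114 expected counts in replicates 1, 2 and 3. A gene is called detected here when it reached a TPM, a level scaled for transcript length and library size, of at least 1 in all 3 libraries. At 1 TPM a protein-coding gene had a median expected count of 59 in replicate 1 (Poisson 95% interval 44.9 to 76.1), 53 in replicate 2 (39.7 to 69.3) and 45 in replicate 3 (32.8 to 60.2). Intervals and floors in this text cover counting error only.

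In total 14418 genes were detected, 12354 of them protein-coding. The protein-coding genes with the highest mean TPM (mean ± SD, n = 3) were MT-ATP8 at 21581 ± 3811, the translation elongation factor EEF1A1 at 12674 ± 604, RPS27 at 9418 ± 322, MT-CO2 at 6567 ± 612 and RPL41 at 5769 ± 92.2. They were followed by MT-CO1 at 5727 ± 595, the RNA-binding protein gene HNRNPA1 at 5476 ± 487, MT-CO3 at 5354 ± 627, RPL11 at 4999 ± 352 and RPS18 at 4992 ± 183. MT-ATP8 overlaps MT-ATP6, and EEF1A1, HNRNPA1 and the ribosomal protein genes have near-identical processed copies in the genome, so the split of reads makes these levels uncertain. TPM also divides by effective length, which is very small for transcripts as short as that of MT-ATP8. The first place of MT-ATP8 is thus no measure of which transcript was most abundant. Mitochondrially encoded genes took 3.10%, 2.43% and 2.80% of the counts in replicates 1, 2 and 3, and ribosomal protein genes took 6.98%, 5.12% and 5.18%. Pearson's r of log2(TPM + 1) across genes, which are not independent replicates, was 0.988 for replicates 1 and 2, 0.985 for replicates 1 and 3 and 0.992 for replicates 2 and 3. The chi-square per degree of freedom between the counts of 2 libraries was 82.4, 82.5 and 19.4 for the same pairs, lowest for replicates 2 and 3.

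Neural progenitor genes were abundant, with 20 of 22 members detected and a list median of 5.37 ± 0.15 log2(TPM + 1) (mean ± SD, n = 3). The highest were VIM, an intermediate filament gene, at 1912 ± 194 TPM, the chromatin protein gene HMGA2 at 387 ± 142 TPM and NES, which encodes nestin, at 181 ± 21.1 TPM. PAX6 (ENSG00000007372.25, chromosome 11, 31789026 to 31817961, GRCh38), a transcription factor gene, was not detected at 0.44 ± 0.34 TPM. The NOTCH target HES5 was not detected either, with 6.76, 0.72 and 5.66 TPM in replicates 1, 2 and 3. SOX2 (ENSG00000181449.4, chromosome 3, 181711925 to 181714436), named after its values were seen, stood at 69.2 ± 26.2 TPM. SOX1, also named after its values were seen, was detected at a lower level, 5.54 ± 2.46 TPM. The mesenchyme list reached a like median (5.55 ± 0.40), and bulk RNA cannot assign the members of either list to a cell type. Among 10000 random lists of protein-coding genes of the same size, the list median lay at percentile 99.99. In replicate 1 the median member lay 0.17 log2 CPM above the mean of the other libraries. It lay 0.47 above once a smooth trend of counts on transcript length was removed in each library, an alternative added after the data were seen.

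Pluripotency genes lay far lower, with 5 of 20 members detected and a list median of 0.11 ± 0.02 (percentile 0.11). The detected members included the RNA-binding protein gene LIN28A (ENSG00000131914.11, chromosome 1, 26410817 to 26429728) at 326 ± 117 TPM, the DNA methyltransferase gene DNMT3B at 59.7 ± 3.39 TPM and L1TD1 at 54.5 ± 18.2 TPM. ESRG and GDF3 had 0 counts in all 3 libraries, which allows up to 0.0514 and 0.152 TPM at 3 counts in the library with the highest floor. The core pluripotency factors POU5F1 (ENSG00000204531.21, chromosome 6, 31164337 to 31170682) at 0.11 ± 0.03 TPM and NANOG at 0.020 ± 0.026 TPM were named after their values were seen. The neural progenitor median exceeded the pluripotency median by 5.26 ± 0.13 log2 units (n = 3).

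Markers of mesoderm, of endoderm, and of epidermis and placode were mostly below detection. Of 12 mesoderm genes only the growth factor receptor gene PDGFRA was detected, at 4.92, 18.1 and 19.03 TPM in replicates 1, 2 and 3. The mesoderm count became 2 at a TPM minimum of 0.5 and 0 at a minimum of 5. KDR at 0.90 ± 0.23 TPM and EOMES at 0.57 ± 0.20 TPM followed, FOXF1 was at 0.0067 ± 0.012 TPM, and HAND1 had 0 counts in all 3 libraries (floor 0.103 TPM). Of 12 endoderm genes only the chemokine receptor gene CXCR4 was detected, at 9.48 ± 1.19 TPM, CER1 was at 0.68 ± 0.67 TPM and APOA1 at 0.39 ± 0.21 TPM, and FOXA2 and HNF4A had 0 counts (floors 0.0670 and 0.0906 TPM). Of 12 epidermis and placode genes 5 were detected, led by the simple-epithelium keratins KRT8 at 65.6 ± 6.84 TPM and KRT18 at 44.1 ± 7.42 TPM and by EYA1 at 18.8 ± 6.06 TPM, while the basal keratins KRT5 and KRT14 had 0 counts (floors 0.212 and 0.170 TPM). List medians were 0.28 ± 0.05 for mesoderm (percentile 3.27), 0.08 ± 0.03 for endoderm (percentile 1.15) and 0.83 ± 0.26 for epidermis and placode (percentile 10.4). The neural progenitor median was higher by 5.09 ± 0.11, 5.29 ± 0.16 and 4.54 ± 0.32 log2 units, respectively (n = 3).

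Neural crest genes were detected in 11 of 12 cases, with a list median of 4.77 ± 0.10 (percentile 96.7). TWIST1 (ENSG00000122691.13, chromosome 7, 19113047 to 19117636), a regulator of cranial mesenchyme, reached 189 ± 48.6 TPM, and the crest factors TFAP2B and TFAP2A reached 58.9 ± 7.14 and 56.7 ± 15.1 TPM, while RET at 1.09 ± 0.37 TPM was not detected. Mesenchyme and fibroblast genes were all detected, 13 of 13, with a list median of 5.55 ± 0.40 (percentile 99.8). The highest were the collagen gene COL1A2 (ENSG00000164692.19, chromosome 7, 94394895 to 94431227) at 278 ± 103 TPM, the homeobox gene PRRX1 at 206 ± 108 TPM and the proteoglycan gene LUM at 166 ± 67.9 TPM. In replicate 1, 10 of the 13 mesenchyme genes had their lowest TPM, and the median member was -0.65 log2 CPM from the mean of the other libraries, against -0.03 for neural crest. With the length trend removed these were -0.43 and 0.21. The neural crest value thus changed its sign.

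The neural progenitor median exceeded the neural crest median by 0.60 ± 0.24 log2 units, in 3 of 3 libraries. Against the mesenchyme list it differed by less than the spread between replicates, at -0.18 ± 0.41, with 0.14, -0.64 and -0.05 in replicates 1, 2 and 3 (exact two-sided sign-flip permutation p = 0.75, n = 3, Benjamini-Hochberg adjusted 0.75). The sign of this difference turned positive in CPM without length scaling (0.30), with members of no other list (0.06) and without replicate 2 (0.05). Of the 15 list differences computed, the other 14 had the same sign in all 3 libraries, and each gave an exact two-sided sign-flip permutation p of 0.25, the smallest that n = 3 allows (adjusted 0.268), so none could reach a threshold of 0.05.

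**Figure D1:**
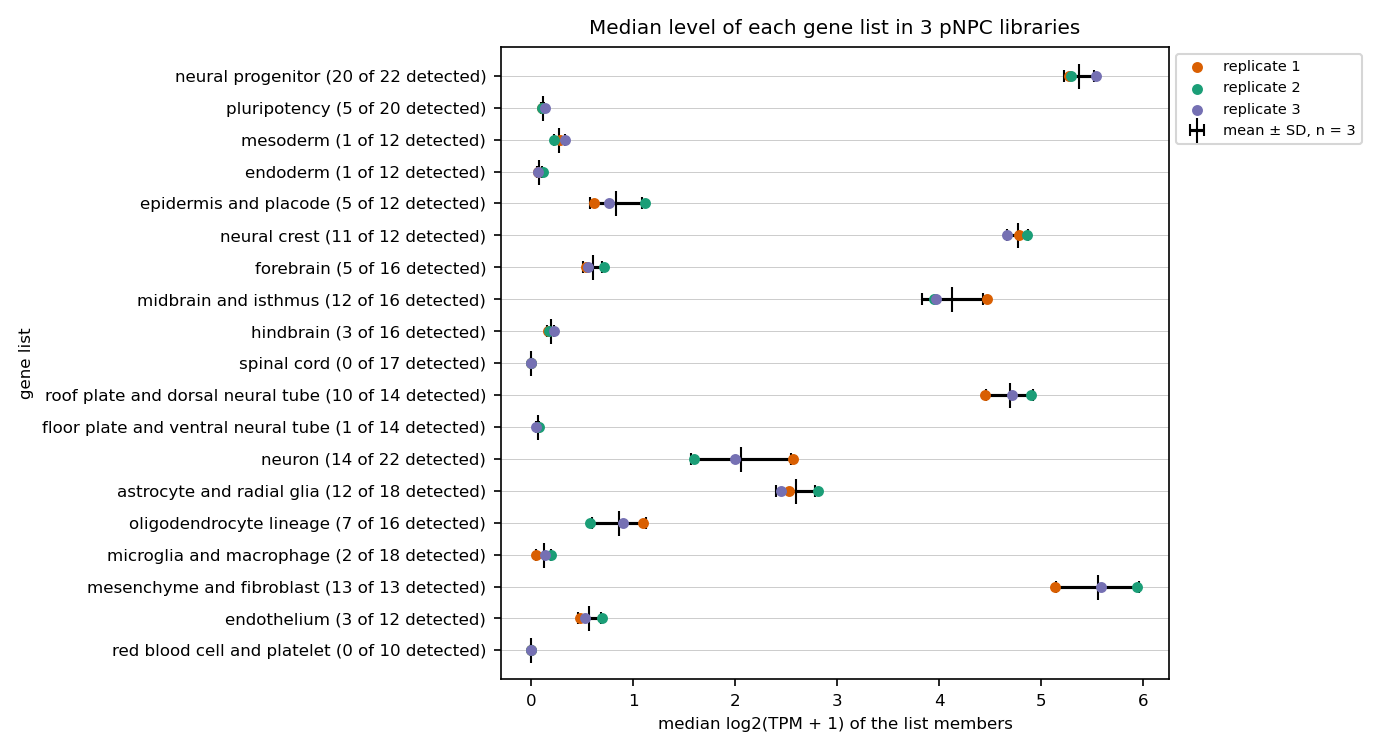
Median log2(TPM + 1) of the members of each identity, regional and lineage list (x axis) in each of the 3 pNPC libraries (coloured points), with the mean and SD over libraries (black bars, n = 3). Neural progenitor (5.37), mesenchyme (5.55), neural crest (4.77), dorsal (4.69) and midbrain and isthmus (4.13) lists lie above 4 on average and every other list shown lies below 3.

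Along the anteroposterior axis, genes of the midbrain and of the isthmus, the signalling centre at the boundary between midbrain and hindbrain, were the highest, with 12 of 16 detected and a list median of 4.13 ± 0.30 (percentile 92.1). PAX8 (ENSG00000125618.18, chromosome 2, 113215997 to 113278921) stood at 106 ± 21.9 TPM and EN2 (ENSG00000164778.4, chromosome 7, 155458129 to 155464831) at 78.0 ± 21.6 TPM. SPRY1 followed at 77.6 ± 15.3 TPM, and EN1 (ENSG00000163064.7, chromosome 2, 118842171 to 118847648) at 39.3 ± 24.0 TPM. PAX7 at 26.6 ± 5.80, PAX5 at 21.6 ± 3.57, IRX3 at 20.7 ± 5.01, LMX1B at 17.9 ± 8.89, SP8 at 8.24 ± 2.5 and PAX2 at 6.80 ± 4.96 TPM were also detected. The isthmic growth factor genes FGF17 and FGF8 stood at 24.0 ± 16.4 and 11.1 ± 9.40 TPM. DMRTA2 was at 0.16 ± 0.12 TPM and BARHL1 had 0 counts (floor 0.0900 TPM). In replicate 1, 9 of the 12 detected genes had their highest TPM and the median member lay 0.75 log2 CPM above the mean of the other libraries (0.92 with the length trend removed), with FGF8 at 21.6, 3.54 and 8.21 TPM and EN1 at 64.8, 35.8 and 17.2 TPM in replicates 1, 2 and 3.

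Forebrain genes were detected in 5 of 16 cases, with a list median of 0.60 ± 0.10 (percentile 5.29). The detected members were the WNT effector TCF7L2 at 25.3 ± 7.11 TPM, DLX2, which is also a gene of cranial neural crest, at 12.5 ± 5.30 TPM, LHX2 at 5.81 ± 3.33 TPM, HESX1 at 4.99 ± 1.05 TPM and EMX2 at 3.91 ± 0.47 TPM. The forebrain genes EMX1 and SIX3 stood at 0.020 ± 0.020 and 0.013 ± 0.012 TPM. OTX2 (ENSG00000165588.19, chromosome 14, 56799905 to 56810479), a forebrain and midbrain factor named after its values were seen, had 0.83, 1.68 and 1.49 TPM in replicates 1, 2 and 3. Hindbrain genes were detected in 3 of 16 cases, namely GBX2 (ENSG00000168505.7, chromosome 2, 236161340 to 236168386), a factor of the anterior hindbrain side of the isthmus, at 61.8 ± 22.3 TPM, IRX2 at 32.8 ± 10.7 TPM and MEIS2 at 13.2 ± 4.18 TPM. HOXA2 had 0 counts (floor 0.0938 TPM), and the hindbrain list median was 0.19 ± 0.03 (percentile 1.08). Of 17 spinal cord genes 0 were detected. CDX1 was the highest of them at 0.24 ± 0.10 TPM, followed by CDX4 at 0.15 ± 0.15 and HOXA7 at 0.11 ± 0.05 TPM, and HOXA4 and HOXA5 had 0 counts (floors 0.123 and 0.197 TPM).

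The forebrain median differed from the midbrain and isthmus median by -3.53 ± 0.37 log2 units (n = 3). The midbrain and isthmus median exceeded the hindbrain median by 3.94 ± 0.32, and the hindbrain median exceeded the spinal cord median of 0 by 0.19 ± 0.03. The sizes depended on the scale. With a pseudocount of 0.1 these 3 differences were -4.92, 6.14 and 1.23, and with the mean of members -2.31, 2.38 and 1.12. The count of forebrain genes depended on the TPM minimum, with 8 detected at a minimum of 0.5 and 2 at a minimum of 5.

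**Figure D2:**
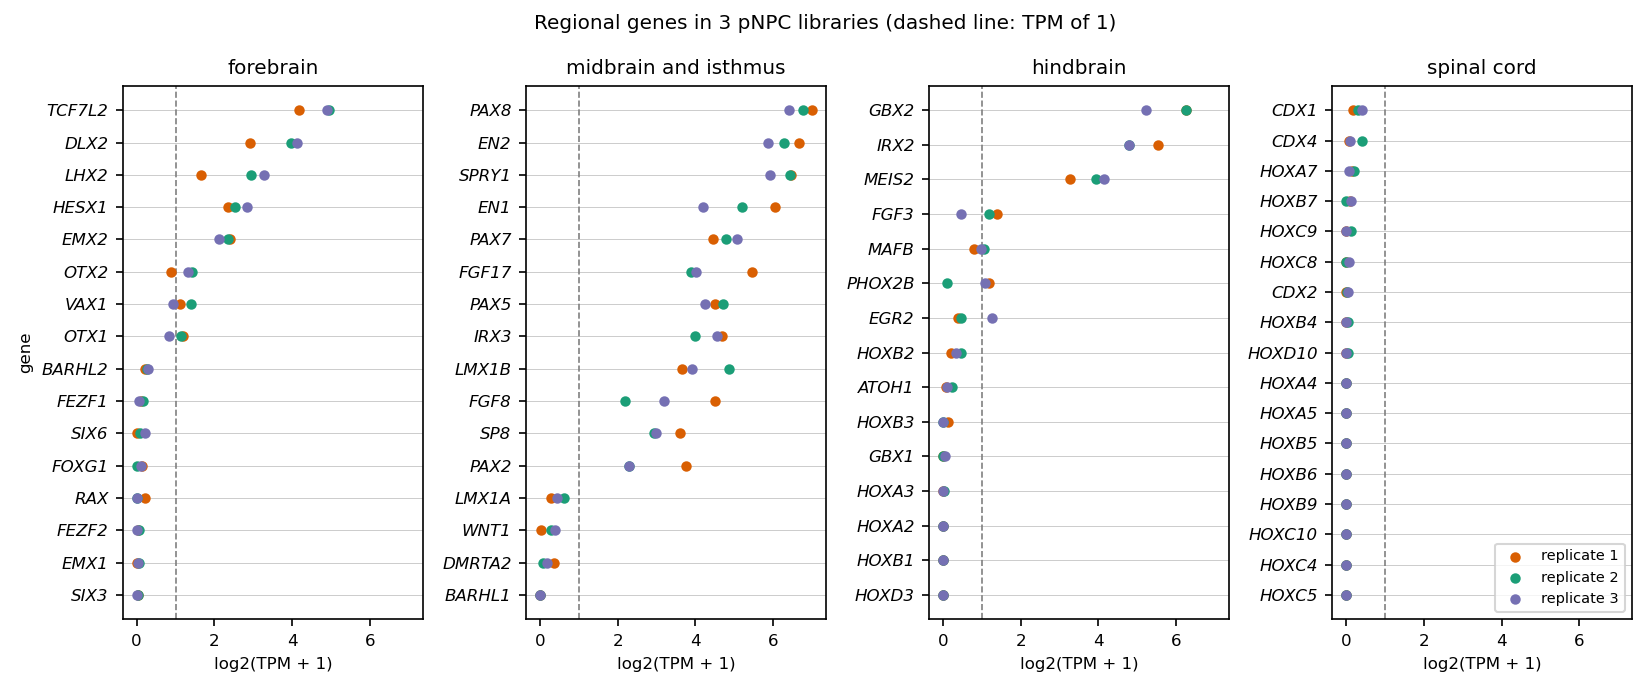
Levels of all but 1 of the genes of the 4 regional lists as log2(TPM + 1) (x axis) in the 3 pNPC libraries (coloured points), with genes ordered by mean TPM and a dashed line at a TPM of 1. Those above the line in all 3 libraries are 12 midbrain and isthmus genes, against 5 forebrain, 3 hindbrain and 0 spinal cord genes.

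Across the dorsoventral axis, genes of the roof plate and dorsal neural tube were high, with 10 of 14 detected and a list median of 4.69 ± 0.23 (percentile 97.5). MSX1 reached 144 ± 64.0 TPM, ZIC2 118 ± 19.7 TPM and ZIC1 99.0 ± 24.8 TPM. The ligand genes BMP4 and BMP7 stood at 52.2 ± 28.3 and 28.4 ± 8.51 TPM and WNT3A at 7.26 ± 4.59 TPM, with MSX2 at 43.9 ± 27.6, PAX3 at 26.5 ± 4.18 and OLIG3 at 20.0 ± 3.61 TPM. LMX1A at 0.38 ± 0.16 TPM and WNT1 at 0.19 ± 0.15 TPM were not detected. Also undetected, and named after their values were seen, were RSPO1 at 0.95 ± 0.43 TPM and GDF7. The latter had 0.99, 2.77 and 1.95 TPM in replicates 1, 2 and 3. PAX3 is also a member of the neural crest list, so the dorsal list is not specific to the neural tube. Of 14 floor plate and ventral genes only PTCH1, a receptor and target of hedgehog signalling, was detected, at 14.0 ± 3.35 TPM. NKX6-1 at 1.03 ± 0.76 and NKX6-2 at 0.44 ± 0.24 TPM followed, and FOXA2 had 0 counts (floor 0.0670 TPM). The ventral list median was 0.06 ± 0.01 (percentile 0.31), and the dorsal median exceeded it by 4.63 ± 0.22 log2 units (n = 3). This difference was 7.43 with a pseudocount of 0.1 and 3.56 with the mean of members. In replicate 1, 7 of the 10 detected dorsal genes had their lowest TPM and the median dorsal member was -0.74 log2 CPM from the mean of the other libraries, and -0.37 with the length trend removed.

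Among later lineages, 14 of 22 neuronal genes were detected, led by the cytoskeletal genes TUBB3 at 375 ± 89.4 TPM and NEFM at 301 ± 163 TPM and by GAP43 at 59.8 ± 11.1 TPM, while SLC17A6 and NEUROG2 stood at 0.080 ± 0.062 and 0.057 ± 0.081 TPM. The neuron list median was 2.05 ± 0.49 (percentile 22.3), and its median member lay 0.85 log2 CPM higher in replicate 1 than in the mean of the other libraries (1.03 with the length trend removed). Astrocyte and radial glia genes were detected in 12 of 18 cases, with GJA1, a gap junction gene, at 178 ± 50.7 TPM, CLU at 102 ± 19.5 TPM and PTPRZ1 at 45.4 ± 2.25 TPM. AQP4, the astrocyte water channel gene, stood at 0.087 ± 0.021 TPM and HOPX had 0 counts (floor 0.138 TPM), and the list median was 2.59 ± 0.19 (percentile 44.1). Of 16 oligodendrocyte lineage genes 7 were detected, with CNP at 83.2 ± 6.38 TPM and SOX10, which also marks neural crest, at 22.2 ± 7.0 TPM. BCAS1 was at 0.033 ± 0.0058 TPM and NKX2-2 had 0 counts (floor 0.0795 TPM). The oligodendrocyte list median was 0.86 ± 0.26 (percentile 7.81), and in replicate 1 its median member lay 0.46 log2 CPM above the mean of the other libraries (0.54 with the length trend removed).

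Genes of blood, vessel and microglial cells were low. Of 18 microglia and macrophage genes 2 were detected, TMEM119 at 15.7 ± 2.76 TPM and IRF8 at 1.58 ± 0.25 TPM, AIF1 had 1.20 ± 0.59 TPM, and the complement gene C1QA and the adaptor gene TYROBP had 0 counts (floors 0.142 and 0.534 TPM). The list median was 0.12 ± 0.07 (percentile 0.17). Of 12 endothelial genes 3 were detected, EGFL7 at 20.9 ± 1.39, ERG at 5.36 ± 2.65 and VWF at 1.5 ± 0.43 TPM, with ICAM2 at 0.017 ± 0.029 and PECAM1 at 0.057 ± 0.090 TPM and a list median of 0.57 ± 0.11 (percentile 5.52). Of 10 red blood cell and platelet genes 0 were detected, with ITGA2B the highest at 1.73 ± 1.08 TPM, ALAS2 at 0.58 ± 0.09 TPM and HBE1 at 0.097 ± 0.17 TPM. HBA1 had 0 counts (floor 0.701 TPM), and the list median was 0 (percentile 0.24). The neural progenitor median exceeded those of neurons by 3.32 ± 0.54, astrocytes and radial glia by 2.78 ± 0.31, the oligodendrocyte lineage by 4.51 ± 0.29, microglia by 5.25 ± 0.15 and endothelium by 4.80 ± 0.20 log2 units (n = 3). At a TPM minimum of 5 the detected counts were 6 for neurons, 4 for the oligodendrocyte lineage and 1 each for microglia and endothelium, and at a minimum of 0.5 they were 4 for microglia and 2 for red blood cell and platelet genes.

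Proliferation genes were detected in 18 of 18 cases, with a list median of 6.99 ± 0.13 that exceeded all 10000 random lists (percentile 100). The replication genes PCNA and TYMS stood at 391 ± 29.5 and 343 ± 20.1 TPM and the mitotic cyclin CCNB1 at 256 ± 1.45 TPM. All 17 p53 target and stress genes were detected, with a list median of 4.64 ± 0.23 (percentile 96.8), among them the stress-response factor ATF4 at 543 ± 39.6 TPM, the chaperone gene HSPA5 at 308 ± 57.5 TPM and BAX at 212 ± 21.0 TPM.

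The medium contained FGF2 at 20 ng/ml, the GSK3 inhibitor CHIR99021 at 3 µM, leukemia inhibitory factor at 10 ng/ml, SB431542, an inhibitor of activin and TGF-beta receptors, at 2 µM and the ROCK inhibitor Y-27632 at 10 µM, and the genes of each pathway were measured without an untreated control. All 14 FGF receptor and feedback genes were detected, with SPRY2 at 100.3 ± 14.0, ETV4 at 93.0 ± 19.1 and FGFR1 at 88.4 ± 15.03 TPM and a list median of 5.56 ± 0.23 (percentile 99.8). WNT receptor and target genes were detected in 16 of 19 cases (median 4.15 ± 0.27, percentile 88.7), with CTNNB1, which encodes beta-catenin, at 339 ± 31.0, GSK3A at 72.1 ± 3.18 and LEF1 at 65.4 ± 15.3 TPM, and LGR5 at 1.01 ± 0.31 and DKK1 at 1.03 ± 0.88 TPM below detection. Of 13 LIF receptor and STAT3 target genes 12 were detected (median 4.07 ± 0.38, percentile 81.6), with STAT3 at 66.1 ± 6.73, TYK2 at 47.7 ± 11.6 and CNTFR at 43.6 ± 8.70 TPM, while LIF itself had 1.19 ± 0.31 TPM. Of 17 TGF-beta and activin genes 12 were detected (median 3.16 ± 0.32, percentile 62.2), with TGFBI at 151 ± 62.3, SMAD2 at 47.0 ± 7.53 and TGFBR1 at 42.1 ± 11.3 TPM, and with ACVR1C at 0.097 ± 0.029 and LEFTY2 at 0.0067 ± 0.012 TPM. ROCK pathway genes were detected in 12 of 12 cases (median 5.40 ± 0.12, percentile 99.5), led by the actin-severing protein gene CFL1 at 1343 ± 165, RHOA at 394 ± 48.1 and MYL12A at 322 ± 54.6 TPM. In replicate 1 the median member was -0.30, -0.36 and -0.38 log2 CPM from the mean of the other libraries for the FGF, LIF and TGF-beta lists. With the length trend removed these were 0.12, -0.11 and -0.06. The sign changed for FGF, and all 3 lay inside the central 95% of random lists matched on abundance.

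Retinoid pathway genes were detected in 13 of 16 cases (median 3.47 ± 0.13, percentile 66.9). The retinoic acid binding protein genes CRABP1 and CRABP2 stood at 852 ± 122 and 806 ± 198 TPM. The synthesis enzymes ALDH1A1 and ALDH1A2 stood at 0.39 ± 0.23 and 0.72 ± 0.31 TPM. A further such enzyme, ALDH1A3, named after its values were seen, was detected at 6.04 ± 1.53 TPM. Of 17 NOTCH pathway genes 14 were detected (median 3.90 ± 0.48, percentile 86.5), with the receptor genes NOTCH2 at 49.2 ± 23.5 and NOTCH3 at 40.8 ± 5.04 TPM and the target HEY1 at 40.5 ± 11.1 TPM, while HEY2 had 1.31 ± 0.41 and HEYL 0.53 ± 0.19 TPM. In replicate 1 the median NOTCH pathway member lay 0.46 log2 CPM above the mean of the other libraries (0.67 with the length trend removed), although NOTCH2 itself was at 22.1, 63.9 and 61.7 TPM in replicates 1, 2 and 3.

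Because the series concerns contacts between neural and microglial cells, ligand and adhesion genes were measured in the pNPCs. Of 18 ligands of microglial receptors 14 were detected (median 4.17 ± 0.20, percentile 93.3), with the cytokine gene MIF at 1201 ± 43.2 TPM, the chemokine gene CCL2 at 392 ± 172 TPM and CD24 at 288 ± 52.0 TPM. IL34, which encodes a ligand of the microglial receptor CSF1R, stood at 0.62 ± 0.30 TPM. CSF1, another ligand of that receptor, named after its values were seen, was detected at 14.3 ± 2.77 TPM, and IL33 had 0 counts (floor 0.0890 TPM). Of 19 neurotrophic and gliogenic ligands 16 were detected (median 2.90 ± 0.58, percentile 50.9), with the heparin-binding growth factor genes MDK at 1884 ± 14.8 and PTN at 247 ± 55.1 TPM and BMP4 at 52.2 ± 28.3 TPM, and with PDGFA at 0.37 ± 0.11 and CTF1 at 0.85 ± 0.19 TPM. The median member of this list was -0.31 log2 CPM from the mean of the other libraries in replicate 1 (-0.22 with the length trend removed). Of 21 neuron-glia adhesion genes 18 were detected (median 3.92 ± 0.19, percentile 84.3), with SPARC at 506 ± 191, NLGN2 at 58.7 ± 9.40 and EFNB1 at 49.7 ± 3.86 TPM, and with CNTN1 and CNTN2 at 0.16 ± 0.08 and 0.12 ± 0.09 TPM. Interferon response genes were detected in 15 of 18 cases (median 3.65 ± 0.08, percentile 76.9), with IFITM3 at 522 ± 67.0, IFITM1 at 263 ± 29.2 and IFNGR2 at 46.6 ± 5.28 TPM, and with IFIT2 at 0.58 ± 0.05 and OAS1 at 0.28 ± 0.03 TPM. At a TPM minimum of 5, 8 retinoid pathway genes and 9 neurotrophic and gliogenic ligands were detected.

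Of the fixed list genes 350 could be tested for more spread between replicates than genes of like abundance, and 26 passed over all genes tested (edgeR goodness of fit, Benjamini-Hochberg adjusted p of at most 0.05), or 47 adjusted over the list alone. For 16 of the 26, replicate 1 was the library farthest from the mean. EN1, PAX2, FGF17, FGF8, SOX3, HES1, HES5, DLL3, STMN2, NEFM, ELAVL4 and TH were called with their highest TPM in replicate 1, for example SOX3 at 85.8, 36.1 and 42.0 TPM in replicates 1, 2 and 3. PDGFRA, COL1A1, COL6A3, THBS1, MSX2, BMP4, WNT3A, NOTCH2, FGFR3, NKD1, CYP26B1 and EGR2 were called with their lowest TPM there, for example COL1A1 at 4.62, 18.3 and 12.9 TPM. GBX2 was called with its lowest TPM in replicate 3. The NOTCH target HES4, with 46.7, 6.26 and 20.5 TPM, had the smallest p of the list genes (edgeR adjusted p = 5.3e-06). Genes of this paragraph outside the naming rule were chosen after their values were seen. With edgeR's moderated F test 0 genes passed, these list genes included. Which of their calls stay with the length trend removed is not reported.

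Over all 17046 genes tested, 271 passed, and replicate 1 was the farthest library for 216 of them, replicate 2 for 25 and replicate 3 for 30. Of the 216 genes, 179 were lower in replicate 1, with a median transcript length of 6013 bases, and 37 were higher there, with a median length of 1423 bases, against 2430 bases over all genes tested. The smallest adjusted p values (edgeR) belonged to TUBA1B-AS1, an antisense gene whose reads cannot be told from those of its partner without strand, at 4.76, 6.21 and 0.59 log2 CPM in replicates 1, 2 and 3 (1.8e-26), and to ZBED6, which lies within the ZC3H11A gene and is uncertain for that reason, at 1.48, 5.82 and 6.41 (1.2e-23). HMCN1, an extracellular matrix gene, had 5.60, 8.03 and 8.56 log2 CPM (edgeR adjusted p = 5.1e-09), AHNAK 5.38, 8.21 and 7.74 (2.4e-08), the neuroendocrine granule gene CHGA 6.36, 3.44 and 5.30 (5.1e-09) and the carbonic anhydrase gene CA4 4.26, 0.45 and 1.63 (3.6e-08). The other 4 of the first 10 were the pseudogene HERC2P2, uncertain because of its near-identical copies, and ENSG00000288534, ENSG00000277067 and ENSG00000285608, which have no symbol in the files. In simulated libraries in which dispersions varied between genes, the test called 198 genes that had not been changed, so the number called measures extra spread of any origin. The count was 0 with edgeR's moderated F test (939 genes had an unadjusted p below 0.05, against 1253 in the goodness of fit test), 98 by DESeq2's dispersion outliers, and 117, 95 and 103 without replicates 1, 2 and 3. By chance alone a share of 0.05 of the 17046 genes tested would have an unadjusted p below 0.05. Neither 939 nor 1253 thus counts genes with excess spread.

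Replicate 1 also differed from the other libraries along transcript length. Protein-coding genes under 1 kb lay 0.34 log2 CPM above the mean of the other libraries (median of 935 genes), those of 3 to 5 kb at -0.15 (3895 genes) and those over 8 kb at -0.75 (428 genes). Over the same classes the medians ran from -0.08 to 0.28 in replicate 2 and from -0.26 to 0.45 in replicate 3. The 3 deviations of a gene sum to 0. The opposite run in the other libraries follows from this centring and is no separate observation. Spearman's rho between a gene's length and its deviation was -0.52, 0.34 and 0.46 in replicates 1, 2 and 3 across 14017 genes, which are not independent replicates. The median gap between a gene's length and its effective length, which grows with the mean fragment or read length of a library, was 216, 253 and 259 bases.

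**Figure D3:**
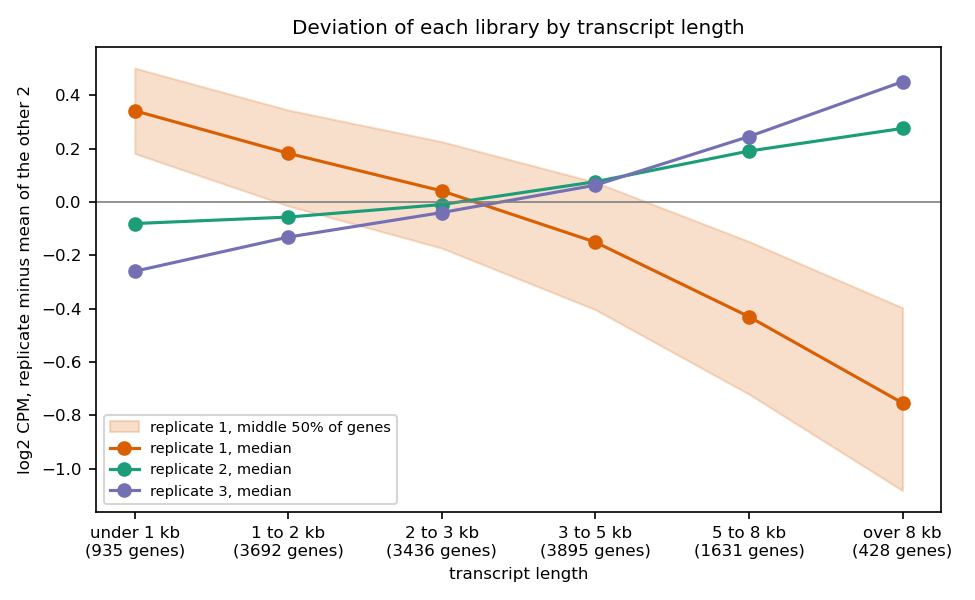
Median difference in log2 CPM between each library and the mean of the other 2 (y axis) for protein-coding genes in 6 classes of transcript length (x axis), with the middle 50% of genes shaded for replicate 1. Replicate 1 runs from 0.34 under 1 kb to -0.75 over 8 kb, and the opposite run of the other libraries follows because the 3 differences of a gene sum to 0.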

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

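The removal of length and GC trends was chosen only after the result was seen, and the other alternatives were planned. The size of the list differences depended on the scale. With a pseudocount of 0.1, neural progenitor minus endoderm went from 5.29 to 8.02. With the mean of members, forebrain minus midbrain and isthmus went from -3.53 to -2.31. Of the recomputed list differences 117 kept their sign, and since n = 3 cannot pass the threshold this says nothing of significance. The 3 that turned all concern neural progenitor minus mesenchyme and fibroblast, at -0.18 as reported, 0.298 in TMM-scaled CPM, 0.0576 with members of no other list, and -0.345 to 0.0468 when each replicate was left out, with the positive value without replicate 2. Leaving out that replicate removes the library with the lowest difference, and otherwise the cause was not tested.

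Detected members moved by over 1.5 times in 13 recounts and stayed within that in 147. At a TPM minimum of 0.5 they were 2 for mesoderm, 8 for forebrain, 4 for microglia and 2 for red blood cell and platelet genes. At a minimum of 5 they were 0 for mesoderm, 2 for forebrain, 6 for neuron, 4 for oligodendrocyte lineage, 1 for microglia, 1 for endothelium, 8 for retinoid and 9 for neurotrophic genes. Red blood cell genes numbered 0 to 1 when each replicate was left out, 1 without replicate 2. The 7 recounts of all detected genes (10464 to 17091) stayed within 1.5 times of 14418.

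The lowest replicate correlation, 0.985, became 0.974 with a pseudocount of 0.1, 0.972 for detected genes only, 0.992 in TMM-scaled CPM and 0.90 as Spearman's rho, and ranged from 0.985 to 0.992 when each replicate was left out. The 271 genes of excess spread became 0 with the moderated F test, which recovered 0% of changed genes in simulations with varying dispersions. In that test 939 genes had an unadjusted p below 0.05, where chance alone would put a share of 0.05 of all genes tested. The 271 genes became 98 by DESeq2's dispersion outliers. They became 95 to 117 when each replicate was left out (117, 95 and 103 without replicates 1, 2 and 3), where 1 residual degree of freedom remains. They were 270 with DESeq2's size factors, 300 without a filter, 271 without mitochondrially encoded genes, 273 with the length trend removed and 230 with the GC trend removed. No paired analysis was possible because there is only 1 group. Depth limits statements on genes near 1 TPM, where 45 to 59 counts were typical.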

Other observations

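Chosen only after the results were seen were the gene families of the next 2 paragraphs, the list deviations with the length trend removed, the choice of the mesenchyme and midbrain lists as a pair, and the tests of length, GC content, depth and fibroblasts.

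Gene families were counted whole, with members in and out of the fixed lists. Of 39 HOX genes 0 were detected, with a summed level of 0.91 ± 0.32 TPM (n = 3) and HOXB2 the highest at 0.27 ± 0.11 TPM, and of 14 NKX homeobox genes 0 were detected. Of 388 olfactory receptor genes, taken as a silent family, 0 were detected. The growth factor genes FGF18 and FGF19 stood at 64.4 ± 29.4 and 24.2 ± 14.0 TPM and the homeobox gene IRX1 at 54.7 ± 24.2 TPM. ZIC5 and ZIC4 stood at 24.3 ± 2.84 and 11.9 ± 1.63 TPM, and 14 of 19 SOX genes were detected.

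Of 6 DLX genes 2 were detected, of 8 LHX genes 3 and of 23 cadherin genes 11. The highest of each family were DLX1 at 16.1, 39.6 and 43.9 TPM in replicates 1, 2 and 3, LHX8 at 7.10, 19.2 and 25.9 TPM and CDH11 at 69.5, 257 and 185 TPM, whereas DLX3, DLX5 and DLX4 stood at 0.73, 0.19 and 0.16 TPM on average. Of other cadherin genes, CDH6 was lowest in replicate 1 as well (25.7, 56.0 and 40.04 TPM), but CDH4 (13.4, 11.4 and 10.6 TPM) and CDH2 (86.9, 81.3 and 89.3 TPM) were not. DLX1 and LHX8 act in cranial mesenchyme and in the ventral forebrain, whose regulator NKX2-1 stood at 0.010 ± 0.017 TPM. Of 44 collagen genes 29 were detected, summing to 1712 ± 403 TPM, with the cartilage collagen gene COL2A1 at 367 ± 80.4 TPM and the basement membrane gene COL4A2 at 159 ± 6.07 TPM. Among guidance genes all 8 ephrins were detected (EFNB3 at 67.5 ± 10.96 TPM), with 9 of 14 Eph receptors (EPHB4 at 60.8 ± 3.94 TPM) and 18 of 20 semaphorins.

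Of the 271 genes of excess spread, 216 had replicate 1 as the farthest library. With the length trend removed, 63.4% of the 216 (137 genes, Wilson 95% interval 56.8 to 69.6) were still called, among 273 calls in all. With the GC trend removed 76.9% (166 genes, 70.8 to 82.0) were still called, among 230 calls in all, with GC content known for 93.5% of the 216. The kept genes thus still spread more than genes of like abundance. The dispersion was estimated anew each time, so a kept call does not measure how much of a deviation went with the trend. How far length or GC content accounts for the 216 genes cannot be told from these shares. The total of replicate 1, 34658454 expected counts, lay between 30038114 and 38400092, so it was neither the shallowest nor the deepest library. These totals were known when depth was chosen as a question, and a rank among 3 libraries cannot exclude an effect of depth. No biological explanation was tested, since the design gives 1 group, and differences between cultures or library preparations stay open.

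In replicate 1 midbrain and isthmus genes lay higher and mesenchyme genes lower, with a gap between the list medians of 1.40 log2, a pair picked because it lay far apart. With the length trend removed the gap was 1.35, 96.5% of its size, and with the GC trend removed 1.25, 89.6%. This argues against either trend as the whole cause of the gap. Each list rose with the length trend removed, midbrain and isthmus from 0.75 to 0.92 and mesenchyme from -0.65 to -0.43. The gap thus does not show how far length accounts for the low mesenchyme level. Of 26 lists with at least 5 members tested, 4 lay above and 6 below the central 95% of matched random lists in replicate 1, and 5 and 3 with the length trend removed, when the FGF, LIF and TGF-beta lists moved inside (percentiles 60.7, 4.06 and 6.93) and the neural progenitor list moved above (100). Other lists moved too, with the neuron list at 0.85 and the NOTCH and oligodendrocyte lists at 0.46 each above the mean of the other libraries and the dorsal list at -0.74 (1.03, 0.67, 0.54 and -0.37 with the length trend removed). The astrocyte and radial glia list was at 0.0046 and the neural crest list at -0.03, and at 0.17 and 0.21 with the length trend removed. A smaller share of mesenchymal cells in replicate 1 is a candidate explanation. Its effect on another list depends on how much of that list's RNA comes from such cells. Bulk RNA does not show this, so the unlike moves of the lists argue neither for nor against this explanation. Changes in several cell types or states stay open as well. No biological explanation was tested because the design gives 1 group.

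Mesenchyme transcripts did not differ from neural progenitor transcripts by more than the spread between replicates, with a median over the 13 members of 34.2, 60.5 and 47.0 TPM in replicates 1, 2 and 3. Fibroblasts of trunk or limb might bring them, and such cells carry HOX transcripts and much COL1A1. HOX genes of groups 4 to 13 summed to 0.31, 0.69 and 0.74 TPM and the ratio of COL1A1 to COL1A2 was at most 0.0495, both low for such cells, but the test rests on an assumed fibroblast profile, so the source cannot be told apart. The same transcripts in progenitors or in derivatives of the anterior cranial neural crest, which lacks HOX expression, also stay open, and bulk RNA cannot assign them to cells.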
